A study of Lactuca sativa with 8 samples.

How the data were processed

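RNA was measured in aerial parts of lettuce seedlings, in 8 libraries of 4 groups of 2 biological replicates. Per the labels, RNA of 6 seedlings per sample was extracted with TRIzol and treated with DNase I, poly(A) RNA was selected, and cDNA was primed with random hexamers. The deposited count table gives raw fragments of each sample on 88978 unigenes assembled by the authors, per the file headers; the aligner, the assembler, the counting tool and their versions are not given in the sources used here. The deposited FPKM values were made by the authors from the same fragments, and they equal the count divided by the unigene length in kilobases and by the library total, on the FPKM scale, within 5e-05. The deposited log2 ratios are the authors' own ratios of normalized group means in 6 comparison tables, and the deposited p-value and FDR columns belong to the same comparisons, with an FDR of at most 0.05 throughout; the tool is not given in the sources used here. All 8 samples were used, no per-sample column belonged to a sample outside these groups (0 such columns), and unigene lengths ran from 224 to 34916 bases (median 908).

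Raw counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, which kept 46562 unigenes, and a robust quasi-likelihood model of all 4 groups with a quasi-likelihood F test for each of the 6 comparisons. All p values of unigenes in the text come from edgeR unless DESeq2 or limma is named, and adjusted p are Benjamini-Hochberg over all tested unigenes, with a bound of 0.05. Standard errors of edgeR values are the size of the log2 change divided by the square root of F, and those of DESeq2 values are the ones DESeq2 gives. With 2 libraries per group the spread is estimated across all 4 groups together. CPM are counts scaled to the effective library size, given as mean ± SD of 2 libraries, and log2 CPM for correlations and principal components used a prior count of 2. Where all libraries of a group had 0 fragments, the fold is given as a lower bound against 3 fragments per library. Library totals of 14.40 to 16.99 M fragments put that floor at 0.163 to 0.235 CPM on this scale.

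The 30 gene lists were search patterns matched to the Swiss-Prot description, or to the Nr description where that was missing, and were tested with camera of limma 3.58.1 against all other tested unigenes, with a preset correlation of 0.01 and also with an estimated correlation, adjusted over the lists. Counts of members are given over all tested unigenes and adjusted over the list alone. A median with bounds replaces each fold against a group at 0 by its bound. The groups, the 6 comparisons, the tests, the 30 lists, the rule for named genes and the alternatives other than those stated as chosen later were chosen before the data were examined.

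Named genes are called unigenes with an informative description whose libraries do not overlap between the compared groups and whose higher group has a mean of at least 50 counts. For each comparison with 0 h the rule takes the 6 largest rises and 6 largest falls, the largest rise and fall of each list, and up to 6 members of the light signalling and of the phenylpropanoid list by size of fold. For the other comparisons it takes the 4 largest rises and falls and the largest rise and fall of each list. The text names part of these. Since the model of all 4 groups called no unigene in the comparisons without 0 h, genes there were taken from DESeq2 1.42.0 or from an edgeR model without the 0 h libraries, which were chosen after the values were seen.

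Library sets were found from unigenes with at least 1 CPM in every library of a set and 0 fragments in all others, at least 100 such unigenes and fewer than 25% Asteraceae among their Nr species. The set was entered as a term of the edgeR model, which leaves the comparisons of 24 h and recovery with 0 h to rest on 6 h as a bridge. That term leaves the comparison of 6 h with 0 h to rest on 6 h replicate 1 and 0 h replicate 2. Overlaps of calls are given beside n1·n2/N, and correlations of log2 changes beside 20 simulations of unchanged groups. In these all libraries, 0 h among them, were drawn anew around 1 mean per unigene, without library sets. For gene lists, leaving out each library in turn and the replicate number as a term were chosen after the data were seen. Other alternatives were DESeq2 size factors, no low-count filter, the replicate number as a term, models of only the compared groups, DESeq2, limma-voom with 1 weight per group, an adjusted p under 0.01, at least 2-fold, Asteraceae best hits alone and leaving out each library in turn. Python 3.11.15, data.table (version 1.17.8) and matplotlib 3.10.9 were used for tables and figures.

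The pipeline was tested on simulated data with the real library sizes and spreads. For 6 h against 0 h it found 0 of 100 unigenes changed 4-fold and 36 of 100 changed 16-fold, with 6 unchanged unigenes among 42 called and 9.7% of unchanged unigenes at an unadjusted p under 0.05. For recovery against 24 h it found 0 of 99 changed 4-fold and 37 of 100 changed 16-fold, with 1 unchanged among 38 called and 0.8% of unchanged unigenes at an unadjusted p under 0.05. At 6 h 100 unigenes per fold were changed among 42941 tested, while 8643 of 46562 were called in the data. The Benjamini-Hochberg bound is stricter with so few changes, so the shares found at 6 h do not give the power there. The 9.7% at 6 h is more than an unadjusted bound of 0.05 allows, so that test was too lenient in the simulation. The 0.8% for recovery against 24 h is less than it allows, so that test was too strict there. A simulated list of 100 unigenes raised 2-fold was called (camera adjusted p = 2.02e-12) and 0 of 9 unchanged lists were. Simulated unigenes vary independently, so this cannot show how camera behaves where members of a list vary together.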

Results

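Aerial parts of lettuce (Lactuca sativa) seedlings of the cultivar Shenxuan 5 were profiled by RNA sequencing before, during and after exposure to ultraviolet-B (UV-B) light. Seedlings 4 weeks old grew at 25 °C under a photoperiod of 14 h of light and 10 h of darkness and were exposed to a 310 nm light-emitting diode at 0.3 W per square metre, per the labels. The 8 libraries fell into 4 groups of 2 biological replicates, each with RNA from 6 seedlings, per the labels. Unexposed seedlings at 0 h were replicates 2 and 3, and the groups after 6 h of UV-B, after 24 h of UV-B and after 12 h of recovery from 24 h of UV-B were each replicates 1 and 2. Between 14.40 and 16.99 M fragments per library were assigned to 88978 assembled transcripts (unigenes), of which 65223 carried a protein description. A unigene with no fragment in a library could still have had up to 0.163 to 0.235 CPM (fragments scaled to the effective library size), the level of 3 fragments, counting error alone being considered. Genes are named by the description of their best protein hit, with the suffix shared by all unigene names left off. Unigenes of 1 cluster (names beginning with CL) can share fragments, so values of single members of a cluster are uncertain.

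Replicates were closest in recovery, with a Pearson correlation of log2 CPM of 0.945 across unigenes, and after 24 h of UV-B (0.936). They were further apart after 6 h (0.883) and furthest at 0 h (0.816). The biological coefficient of variation was 0.730 between the 0 h libraries and 0.360 between the recovery libraries. The 100 most abundant unigenes held 42.8% of the fragments in 0 h replicate 3 and 26.4% in 0 h replicate 2. Replicate 2 after 6 h correlated best with replicate 1 after 24 h (0.919), and every other library correlated best with its own partner. Principal component 1 held 49.4% of the variance and separated both 0 h libraries from the other 6.

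**Figure D1:**
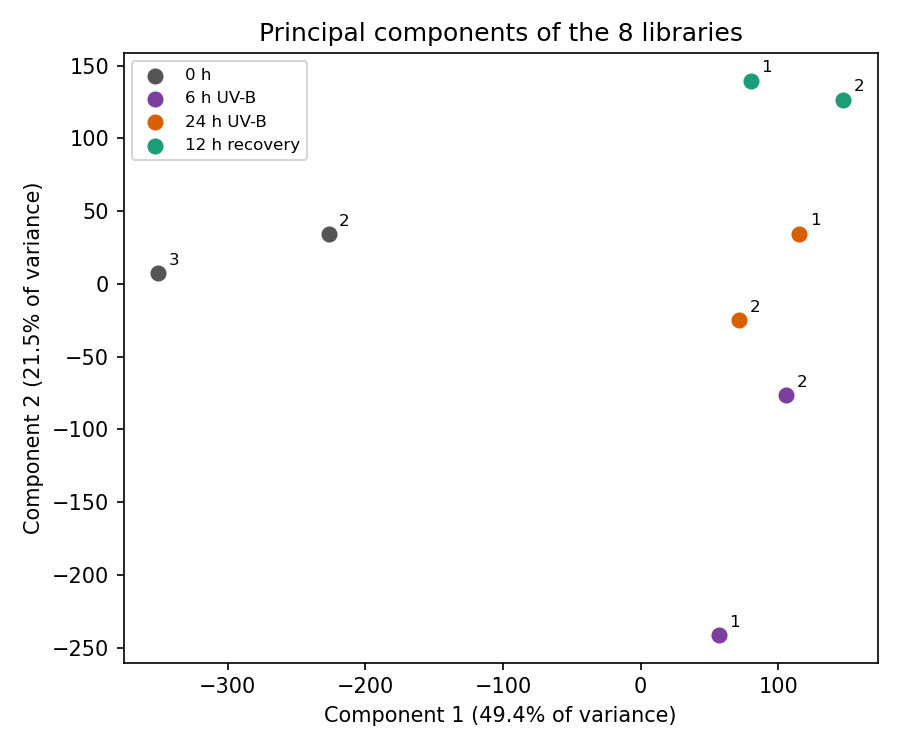
Principal components of log2 CPM over 46562 unigenes, 1 point per library, with component 1 (49.4% of variance) on the horizontal and component 2 (21.5%) on the vertical axis. The 0 h libraries lie at -226.6 and -350.7 on component 1 and the other 6 libraries between 56.7 and 147.3.

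Sequences whose best hits were proteins of other organisms divided the libraries into 3 sets that did not follow the groups. Set A, of 522 unigenes, was present in 0 h replicate 2 and 6 h replicate 1 and without a fragment in the other libraries. Of the 501 with a named species, 264 had a best hit in tobacco (Nicotiana) and 3 in the daisy family (Asteraceae), to which lettuce belongs. Set B, of 312 unigenes, was found in 0 h replicate 3 alone, with 121 best hits in grasses and 81 in algae and oomycetes. Set C, of 174 unigenes, was found in 6 h replicate 2 and in all libraries of 24 h and recovery, with 42 best hits in grasses, 34 in lotus (Nelumbo) and 33 in algae and oomycetes. These unigenes took between 0.0554% and 0.305% of the fragments of the libraries that held them. Among all other unigenes 61.5% of the named species were Asteraceae. The comparisons of 24 h and of recovery with 0 h therefore set libraries of different sets against each other throughout, while at 6 h 1 pair of libraries, 6 h replicate 1 and 0 h replicate 2, lay within a set. Values with the set as a term come from a model that also holds the 3 sets. In that model only the 6 h libraries link 24 h and recovery to 0 h. Its change at 6 h is that of 6 h replicate 1 over 0 h replicate 2, the pair within set A, 1 library each. Values with the set as a term at 6 h and medians within set A are therefore not separate evidence. Its changes of 24 h and recovery against 6 h rest on 6 h replicate 2 alone. The spread in it comes from the replicates of 24 h and recovery.

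**Figure D2:**
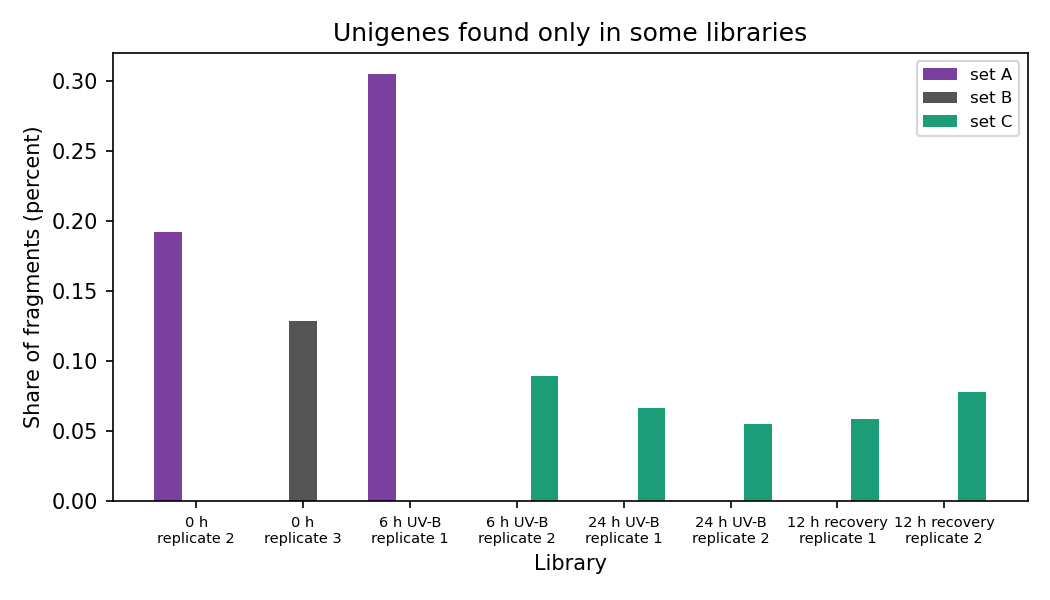
Share of fragments (percent, linear axis from 0) that each of the 8 libraries assigned to the 3 sets of unigenes with best hits mainly outside the Asteraceae. Bars of set A stand only at 0 h replicate 2 (0.192%) and 6 h replicate 1 (0.305%), the bar of set B only at 0 h replicate 3 (0.129%), and those of set C at the other 5 libraries.

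The 6 h group was compared with 0 h, which differs from it in hours since the start as well as in exposure. The lists of WRKY, ethylene, jasmonate and NAC genes were higher without the set as a term and in each model without 1 library, but not with an estimated correlation (adjusted p = 0.476 for each). With that term, which at 6 h compares 6 h replicate 1 with 0 h replicate 2 alone, they were higher too. Phenylpropanoid enzymes were higher with and without that term, but not without 0 h replicate 2, the 0 h library that the term rests on. They were not called with an estimated correlation either (adjusted p = 0.476). The defence list was higher and the photosynthesis list lower only without that term and only with 0 h replicate 3. Neither was called with an estimated correlation (adjusted p = 0.570 and 0.476). Single genes of light signalling fell. Flavonoid 3'-monooxygenase (CL3170.Contig1), which hydroxylates the B ring of flavonoids, rose from 2.48 ± 2.17 to 623 ± 84.8 CPM (log2 change 7.96 ± 0.94, adjusted p = 0.00694; mean ± SD, n = 2, and log2 change ± SE from edgeR). Chitinase II (Unigene16993), an enzyme that degrades fungal cell walls, rose from 1.12 ± 0.292 to 531 ± 16.5 CPM (log2 change 8.88 ± 0.65, adjusted p = 0.00643). A chloroplast small heat shock protein (Unigene21701) was at least 175-fold higher (adjusted p = 0.00930), since no fragment of it was found at 0 h. The transcription factor HY5 (Unigene5496), a positive regulator of light responses, fell from 21.6 ± 1.96 to 2.91 ± 0.0316 CPM (log2 change -2.89 ± 0.51, adjusted p = 0.0141). In all, 8643 of 46562 tested unigenes changed, 5150 higher and 3493 lower, by edgeR with adjusted p under 0.05, each by at least 2-fold. On simulated data the test of 6 h against 0 h was too lenient, so this count may hold more false calls than the bound allows.

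Of the phenylpropanoid and flavonoid enzymes, 19 of 74 rose and 3 fell, and 20 and 3 adjusted over the list alone (median log2 change 0.50, camera adjusted p = 0.00712, adjusted p = 0.476 with an estimated correlation). The median within set A (6 h replicate 1 over 0 h replicate 2) was 2.07. With the set as a term, which rests on the same pair of libraries, the median was 2.66. Without 0 h replicate 2, the only 0 h library of that pair, the list was not called. Leucoanthocyanidin dioxygenase (CL9026.Contig1), an enzyme of anthocyanin synthesis, had a log2 change of 8.19 ± 1.44, adjusted p = 0.0142. Values were 4.95 ± 0.64 for 4-coumarate-CoA ligase-like 5 (CL10209.Contig2), 5.37 ± 0.97 for flavonoid 3',5'-hydroxylase 2 (Unigene426) and 6.80 ± 1.30 for anthocyanidin 3-O-glucosyltransferase 2 (CL860.Contig7). A unigene described as flavonol synthase/flavanone 3-hydroxylase (CL10894.Contig1) had a log2 change of -5.88 ± 1.51, adjusted p = 0.0364, or -3.94 with an adjusted p of 0.145 with the set as a term. Among lignin and chlorogenic acid enzymes 18 of 96 rose and 9 fell (23 and 13 adjusted over the list alone; median 0.58, camera adjusted p = 0.165, 0.251 with the set as a term). Caffeic acid 3-O-methyltransferase (CL1671.Contig1), which methylates lignin precursors, rose from 1.11 ± 0.692 to 228 ± 145 CPM (log2 change 7.64 ± 0.87, adjusted p = 0.00677), and caffeoylshikimate esterase (CL11194.Contig1) had a log2 change of -4.52 ± 0.84.

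Of the UV-B and light signalling genes 2 of 123 rose and 9 fell, and 0 and 3 adjusted over the list alone (median -0.17, camera adjusted p = 0.249). A pair of unigenes described as the UV-B photoreceptor UVR8 rose, Unigene17383 from 0.443 ± 0.184 to 11.2 ± 3.09 CPM (log2 change 4.61 ± 1.17, adjusted p = 0.0353) and Unigene4762 with a log2 change of 3.35 ± 0.92, adjusted p = 0.0427. Neither passed the test when any 1 of the 4 libraries was left out. The ubiquitin ligase COP1 (Unigene27280), which interacts with UVR8, had a log2 change of -3.10 ± 0.78, adjusted p = 0.0345. Its partner SPA1-related 4 (CL3330.Contig14) had -3.87 ± 0.66 and the blue-light receptor phototropin-1 (CL6080.Contig1) -2.52 ± 0.65. The circadian clock list was lower by camera (median -0.84, adjusted p = 0.0415, adjusted p = 0.476 with an estimated correlation, 0.0489 with the set as a term). It was not called when any 1 of the 4 libraries was left out (adjusted p up to 0.127). In it 2 of 79 rose and 2 fell, and 0 and 0 adjusted over the list alone, with LUX (Unigene7894), a component of the evening complex, at 2.99 ± 0.67 and ELF4-like 3 (CL8134.Contig1) at -2.04 ± 0.56.

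Transcription factors of the WRKY family, many of which act in defence, showed the lowest camera p of the 30 lists at 6 h. Of these factors 50 of 150 rose and 3 fell, and 69 and 7 adjusted over the list alone (median 1.78, or 1.74 with bounds for members at 0; adjusted p = 5.00e-11; adjusted p = 0.476 with an estimated correlation; 7.95e-07 with the set as a term; within set A 1.78). WRKY55 (CL10932.Contig1) was at least 65.6-fold higher. Of the defence and pathogenesis-related genes 97 of 551 rose and 23 fell, of NAC factors 23 of 107 rose and 3 fell, of ethylene genes 60 of 246 rose and 8 fell and of jasmonate genes 26 of 103 rose and 1 fell. The counts adjusted over the list alone were 105 and 27, 29 and 3, 72 and 14, and 27 and 8. All 4 lists were higher by camera (adjusted p = 0.0115, 2.72e-04, 4.55e-05 and 0.00219). With an estimated correlation the adjusted p was 0.570 for defence and 0.476 for the other lists, and with the set as a term 0.223, 0.0146, 0.00329 and 0.00709. NAC72 (Unigene14612), a factor induced by drought and abscisic acid, rose from 0.664 ± 0.276 to 38.7 ± 13.8 CPM (log2 change 5.83 ± 0.74, adjusted p = 0.00781). ERF14 (Unigene16554) was at least 46.3-fold and 12-oxophytodienoate reductase 1 (CL8061.Contig5) at least 33.6-fold higher. The ethylene-responsive factor WIN1 (Unigene31517), an activator of wax synthesis, had a log2 change of -6.85 ± 1.06, adjusted p = 0.0133.

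Of the nuclear photosynthesis genes 2 of 331 rose and 49 fell, and 1 and 30 adjusted over the list alone (median -1.27, camera adjusted p = 2.34e-04, adjusted p = 0.476 with an estimated correlation). The median was -0.91 against 0 h replicate 2 and -1.85 against replicate 3, and 0.00 within set A. Leaving out 0 h replicate 3 ended the call (adjusted p = 0.0574). With the set as a term the list was not lower (median 0.00, adjusted p = 0.720, direction upward). Among its members with an Asteraceae best hit, 2 of 128 rose and 31 fell, with a median of -2.23, or -0.54 within set A. A Rubisco small chain (Unigene4630), part of the enzyme that fixes carbon dioxide, fell from 96.9 ± 56.7 to 0.944 ± 0.690 CPM (log2 change -6.66 ± 1.30, adjusted p = 0.0185). In the opposite direction, photosystem I subunit II (CL6494.Contig1) was at least 148-fold higher, with no fragment at 0 h. Of the chlorophyll and carotenoid genes 1 of 102 rose and 19 fell, and 1 and 19 adjusted over the list alone (median -1.22, camera adjusted p = 9.02e-05; 0.492 as an adjusted p with an estimated correlation and 0.223 with the set as a term). Zeaxanthin epoxidase (Unigene6726) had a log2 change of -6.19 ± 1.16, and glutamyl-tRNA reductase 1 (CL1157.Contig1), the first enzyme of chlorophyll synthesis, 3.35 ± 0.76.

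Root and vascular markers (12 of 38 rose and 0 fell), terpenoid and sesquiterpene lactone enzymes (20 of 79 rose and 12 fell) and microbial and animal sequences (43 of 174 rose and 9 fell) were also higher by camera, and cell cycle and histone genes (8 of 324 rose and 32 fell) lower. Adjusted over the list alone the counts were 12 and 0, 29 and 15, 56 and 19, and 0 and 4. Their camera adjusted p were 2.49e-04, 0.0123, 0.0235 and 0.00705, each 0.476 as an adjusted p with an estimated correlation, and 0.00126, 0.223, 0.747 and 0.223 with the set as a term. Of the 174 microbial and animal sequences 156 were described as transposon or retrovirus proteins, and 41 of these rose. The Casparian strip membrane protein 1 (Unigene10574), of the root endodermis, was at least 19.4-fold higher and germacrene A synthase (CL610.Contig6), the first enzyme of sesquiterpene lactone synthesis, had a log2 change of 7.96 ± 0.88, adjusted p = 0.00643. Glutathione S-transferase U24 (CL5882.Contig6), a detoxifying enzyme, was at least 129-fold higher and the transporter ABCG36 (Unigene14908) at least 86.6-fold. The largest falls included bHLH61 (CL10088.Contig1), at least 110.4-fold lower, and the sugar transporter SWEET9 (CL1562.Contig2), at least 28.8-fold lower.

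The other 15 lists were not called at 6 h by camera (adjusted p from 0.102 to 0.854). They included the heat shock proteins (31 of 444 rose and 35 fell), antioxidant enzymes (34 of 353 rose and 25 fell) and DNA repair genes (13 of 146 rose and 14 fell). The same held for abscisic acid genes (25 of 264 rose and 26 fell), auxin genes (30 of 205 rose and 17 fell) and gibberellin and brassinosteroid genes (16 of 97 rose and 14 fell). Further such lists were the MYB factors (28 of 199 rose and 16 fell), bHLH factors (13 of 140 rose and 19 fell), cell wall genes (28 of 264 rose and 23 fell) and ribosomal proteins (5 of 513 rose and 9 fell). The remaining lists were senescence genes (10 of 132 rose and 7 fell), latex and wound markers (7 of 60 rose and 3 fell), flower and pollen markers (11 of 105 rose and 10 fell), the transcripts of the plastid and mitochondrial genomes (17 of 143 rose and 16 fell) and reference genes (7 of 247 rose and 7 fell). With the set as a term the ribosomal list was higher (adjusted p = 0.00234). Without 0 h replicate 3 no list was called lower at 6 h: chlorophyll and carotenoid genes had an adjusted p of 0.0602, and defence genes (0.211) and microbial and animal sequences (0.0697) were not called higher. Cell cycle genes reached 0.109 without 6 h replicate 2. In the model with the set as a term the 6 h change is that of 6 h replicate 1 over 0 h replicate 2. Of the 8643 unigenes called without the term, 3819 were called with it, all in the same direction. Both libraries also enter the model without the term, so the shared direction is not separate evidence. Leaving out 6 h replicate 1 gave 2101 calls (1993 higher, 108 lower) and replicate 2 1773 (1601 higher, 172 lower). A model of these 2 groups alone gave 0 by edgeR, with 11825 unigenes at an unadjusted p under 0.05. In models of all 4 groups limma-voom called 1643 (1106 higher, 537 lower) and DESeq2 12349.

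After 24 h of UV-B, genes of photosynthesis were lower than at 0 h in larger number, and WRKY and NAC factors and single defence, wound and flavonoid genes were higher. With an estimated correlation the photosynthesis, WRKY and NAC lists were not called (camera adjusted p = 0.289, 0.289 and 0.479). The NAC list was not called without 0 h replicate 3 either. Chlorophyll a-b binding protein 1D (Unigene29065), a light-harvesting protein, fell from 724 ± 979 to 0.262 ± 0.0131 CPM (log2 change -11.39 ± 2.09, adjusted p = 0.0209). A thaumatin-like protein (Unigene12189), of a family of pathogenesis-related proteins, rose from 5.15 ± 4.45 to 2876 ± 190.5 CPM (log2 change 9.13 ± 1.14, adjusted p = 0.00956). Polyphenol oxidase II (Unigene9544), which oxidises phenols after wounding, rose from 2.07 ± 0.157 to 878 ± 439.5 CPM (log2 change 8.72 ± 0.90, adjusted p = 0.00780). The UVR8-described Unigene17383 rose from 0.443 ± 0.184 to 108 ± 130.4 CPM (log2 change 7.88 ± 1.32, adjusted p = 0.0165). In all 5625 unigenes changed, 3542 higher and 2083 lower, by edgeR with adjusted p under 0.05.

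Of the photosynthesis genes 2 of 331 rose and 90 fell, and 17 and 143 adjusted over the list alone (median -3.79, or -3.01 with bounds; camera adjusted p = 1.26e-12; adjusted p = 0.289 with an estimated correlation; 1.54e-04, and a median of -0.59, with the set as a term). Over the 128 members with an Asteraceae best hit the median was -3.26, or -1.26 with that term. Without that term the median over all members was -1.82 against 0 h replicate 2 and -2.30 against replicate 3. Of the chlorophyll and carotenoid genes 1 of 102 rose and 13 fell, and 1 and 18 adjusted over the list alone (median -1.61, camera adjusted p = 3.56e-06; adjusted p = 0.479 with an estimated correlation; 0.102 with the set as a term). Zeaxanthin epoxidase (CL10571.Contig1), of the xanthophyll cycle, had a log2 change of -5.42 ± 0.91, adjusted p = 0.0165, and pheophytinase (CL2461.Contig4), an enzyme of chlorophyll breakdown, 2.12 ± 0.48. Clock genes were lower by camera (median -1.03, adjusted p = 0.00150; adjusted p = 0.289 with an estimated correlation; 8.31e-04 with the set as a term), and 6 of 79 rose and 14 fell, with 7 and 30 adjusted over the list alone. CCA1 (CL7209.Contig2), a morning-phased clock factor, had a log2 change of 4.86 ± 0.69, adjusted p = 0.0113, and the daytime-phased pseudo-response regulator APRR7 (CL1008.Contig8) -3.37 ± 0.78, adjusted p = 0.0356.

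Of the WRKY factors 36 of 150 rose and 1 fell (47 and 4 adjusted over the list alone), and of NAC factors 12 of 107 rose and 0 fell (12 and 0 adjusted over the list alone). Of the defence genes 70 of 551 rose and 18 fell (83 and 23 adjusted over the list alone), and of ethylene genes 42 of 246 rose and 7 fell (50 and 14 adjusted over the list alone). These lists were higher by camera (adjusted p = 1.75e-07, 0.00171, 0.0305 and 0.0242). With an estimated correlation the adjusted p were 0.289, 0.479, 0.660 and 0.479, and with the set as a term 2.16e-05, 0.00795, 0.414 and 0.160. WRKY31 (CL7285.Contig1) had a log2 change of 8.26 ± 0.96, adjusted p = 0.00833 and NAC90 (CL2969.Contig2) 5.81 ± 0.94, adjusted p = 0.0153. The ethylene-forming enzyme 1-aminocyclopropane-1-carboxylate synthase 9 (Unigene14803) was at least 30.8-fold and MYB108 (CL9422.Contig1), a factor of wounding and senescence, at least 35.4-fold higher. Pathogenesis-related protein 1 (Unigene19947) was at least 877-fold lower, with 1.32 CPM in 0 h replicate 2 and 308 in replicate 3. The cold-induced factor DREB1A (CL5091.Contig2) was at least 234-fold lower, and abscisic acid 8'-hydroxylase 4 (Unigene13776), which breaks down abscisic acid, had a log2 change of -6.43 ± 0.68, adjusted p = 0.00788.

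Lignin and chlorogenic acid enzymes were higher (17 of 96 rose and 7 fell; 31 and 9 adjusted over the list alone; camera adjusted p = 0.0140; adjusted p = 0.479 with an estimated correlation; 0.00489 with the set as a term), with caffeic acid 3-O-methyltransferase (CL1671.Contig1) at 6.09 ± 0.82. Of the phenylpropanoid and flavonoid enzymes 14 of 74 rose and 4 fell, and 24 and 17 adjusted over the list alone, with a median of 0.28, a mean of -0.52 and a camera adjusted p of 0.148 upward. With the set as a term the median was 1.73 and the adjusted p 8.31e-04 upward. Flavonoid 3'-monooxygenase (CL3170.Contig1) rose from 2.48 ± 2.17 to 672 ± 245 CPM (log2 change 8.07 ± 0.95, adjusted p = 0.00864), while flavonoid 3-O-glucosyltransferase 6 (Unigene13796) had -5.53 ± 0.69, adjusted p = 0.00956. Scopoletin glucosyltransferase (Unigene12862), which stores the coumarin scopoletin as a glucoside, was at least 124-fold and alpha-dioxygenase 1 (Unigene1378), which oxidises fatty acids, at least 109-fold higher. Of the UV-B and light signalling genes 2 of 123 rose and 5 fell, and 1 and 5 adjusted over the list alone (camera adjusted p = 0.254). HY5 (Unigene5496) had a log2 change of -2.71 ± 0.50, adjusted p = 0.0210 and phototropin-2 (CL4541.Contig2) -2.07 ± 0.47, adjusted p = 0.0340.

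Terpenoid enzymes (18 of 79 rose and 0 fell; 26 and 1 adjusted over the list alone) and root and vascular markers (11 of 38 rose and 0 fell; 13 and 1 adjusted over the list alone) were higher by camera (adjusted p = 0.00184 and 0.00171). So were ribosomal proteins (3 of 513 rose and 0 fell; 0 and 0 adjusted over the list alone) and microbial and animal sequences (19 of 174 rose and 2 fell; 19 and 2 adjusted over the list alone), with adjusted p of 0.0242 and 0.0410. Cell cycle genes (3 of 324 rose and 13 fell; 0 and 0 adjusted over the list alone) and bHLH factors (10 of 140 rose and 18 fell; 14 and 23 adjusted over the list alone) were lower (adjusted p = 0.00256 and 0.0266). Cell wall genes (23 of 264 rose and 26 fell; 27 and 38 adjusted over the list alone), antioxidant enzymes (19 of 353 rose and 16 fell; 19 and 12 adjusted over the list alone) and reference genes (2 of 247 rose and 11 fell; 0 and 2 adjusted over the list alone) were lower too. Their adjusted p were 0.0305, 0.0305 and 0.0424. For these 9 lists the adjusted p with an estimated correlation ran from 0.289 to 0.686, and with the set as a term root and vascular markers (0.00489) and ribosomal proteins (0.00284) stayed under 0.05. With that term the cell wall list pointed upward (median 0.69, adjusted p = 0.399) and the antioxidant list had a median of 0.23 (adjusted p = 0.990). Germacrene A synthase (CL610.Contig1) was at least 40.7-fold higher, the root cap protein CL3111.Contig1 had a log2 change of 10.86 ± 1.96, ribosomal protein L44 (CL381.Contig4) 2.66 ± 0.46, and the auxin-responsive SAUR24 (Unigene20031) -8.00 ± 1.20. Of the 17 lists called at 24 h, 8 stayed called in each model without 1 library: photosynthesis, chlorophyll and carotenoid, clock, WRKY, lignin, terpenoid, root and vascular, and cell cycle. The largest adjusted p of the other 9 were 0.0529 for NAC, 0.124 for ethylene, 0.428 for defence, 0.501 for antioxidant, 0.486 for cell wall and 0.191 for microbial and animal sequences, all without 0 h replicate 3. They were 0.197 for reference genes and 0.905, with the direction turned, for ribosomal proteins without 0 h replicate 2, and 0.0759 for bHLH without 24 h replicate 1. With the library set as a term edgeR called 0 unigenes at 24 h, with 10190 at an unadjusted p under 0.05. Without that term limma-voom called 1783 (883 higher, 900 lower) and DESeq2 10059 (5698 higher, 4361 lower). Leaving out 24 h replicate 1 gave 579 calls (566 higher, 13 lower), 24 h replicate 2 1052 (1001 higher, 51 lower) and 0 h replicate 2 10427, and a model of these 2 groups alone gave 2136.

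After 12 h of recovery from 24 h of UV-B, photosynthesis genes remained below the 0 h level and single genes of flavonoid, terpenoid and wound metabolism above it. The photosynthesis list was not called with an estimated correlation (camera adjusted p = 0.414). Its median went from -4.21 to -0.78 with the set as a term. Flavonoid 3'-monooxygenase (CL3170.Contig1) stood at 968 ± 350.5 CPM against 2.48 ± 2.17 at 0 h (log2 change 8.59 ± 0.97, adjusted p = 0.0104). The UVR8-described Unigene17383 stood at 632 ± 85.5 against 0.443 ± 0.184 CPM (log2 change 10.43 ± 1.45, adjusted p = 0.0129). A 3-hydroxy-3-methylglutaryl-coenzyme A reductase (CL4083.Contig2), which controls the mevalonate pathway to sesquiterpenes, rose from 3.91 ± 0.995 to 367 ± 25.9 CPM (log2 change 6.55 ± 0.61, adjusted p = 0.00877). Chlorophyll a-b binding protein 21 (CL432.Contig6) fell to 0.127 ± 0.0785 CPM, from 53.8 in 0 h replicate 2 and 2277 in replicate 3 (log2 change -13.04 ± 2.39, adjusted p = 0.0192). In all 7278 unigenes changed, 4059 higher and 3219 lower, by edgeR with adjusted p under 0.05.

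Of the photosynthesis genes 2 of 331 rose and 114 fell, and 24 and 156 adjusted over the list alone (median -4.21, or -3.12 with bounds; camera adjusted p = 9.36e-13; adjusted p = 0.414 with an estimated correlation; 2.68e-06, and a median of -0.78, with the set as a term). Over the 128 members with an Asteraceae best hit the median was -3.48, or -1.84 with that term. Without that term the median over all members was -2.31 against 0 h replicate 2 and -2.42 against replicate 3. Of the chlorophyll and carotenoid genes 1 of 102 rose and 24 fell, and 1 and 35 adjusted over the list alone (camera adjusted p = 1.56e-06; adjusted p = 0.563 with an estimated correlation; 0.0202 with the set as a term). Pheophytinase (CL2461.Contig4) rose from 2.89 ± 0.117 to 25.5 ± 0.758 CPM (log2 change 3.14 ± 0.50, adjusted p = 0.0148), and prolycopene isomerase (Unigene4242), of carotenoid synthesis, was at least 30.8-fold lower. Clock genes were lower (7 of 79 rose and 17 fell; 7 and 21 adjusted over the list alone; camera adjusted p = 0.0159; adjusted p = 0.543 with an estimated correlation; 0.00815 with the set as a term), with CCA1 (CL7209.Contig2) at 5.62 ± 0.69 and the pseudo-response regulator PRR73 (CL1008.Contig4) at -3.42 ± 0.85.

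Of the UV-B and light signalling genes 9 of 123 rose and 9 fell, and 9 and 9 adjusted over the list alone (camera adjusted p = 0.540). Another UVR8-described unigene (Unigene4762) had a log2 change of 5.08 ± 0.97, adjusted p = 0.0208, and the B-box factor BBX19 (Unigene6073), a regulator of seedling light responses, 3.47 ± 0.71, adjusted p = 0.0244. HY5 (Unigene5496) fell from 21.6 ± 1.96 to 1.31 ± 0.735 CPM (log2 change -4.03 ± 0.54, adjusted p = 0.0121), and COP1 (Unigene27280) had -3.54 ± 0.80, adjusted p = 0.0293. Of the phenylpropanoid and flavonoid enzymes 11 of 74 rose and 7 fell, and 14 and 15 adjusted over the list alone, with a median of -0.45, a mean of -0.92 and a camera direction upward (adjusted p = 0.510). With the set as a term the same list had a median of 1.22 and an adjusted p of 0.00271 upward. A chalcone synthase (CL4574.Contig5), the first enzyme of flavonoid synthesis, had a log2 change of -7.67 ± 1.93, adjusted p = 0.0380, with 8.02 CPM in 0 h replicate 2 and 258 in replicate 3. Leucoanthocyanidin dioxygenase CL9596.Contig1 had -8.56 ± 2.32, adjusted p = 0.0459, with 5.50 and 1407 CPM in these libraries, and 0.13 (adjusted p = 1.000) with the set as a term.

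Polyphenol oxidase II (Unigene9544) rose from 2.07 ± 0.157 to 1497 ± 959.6 CPM (log2 change 9.49 ± 0.93, adjusted p = 0.00924), laccase-7 (CL4812.Contig2), which polymerises phenols, had 10.43 ± 0.88, adjusted p = 0.00877, and the senescence regulator Unigene10027 6.28 ± 1.00, adjusted p = 0.0152. Scopoletin glucosyltransferase (Unigene12862) was at least 179.7-fold higher, as were the ACT domain protein ACR2 (CL2039.Contig3) by at least 378-fold and the actin bundler fimbrin-5 (Unigene405) by at least 235-fold. The DELLA protein RGL1 (CL5302.Contig4), a repressor of gibberellin responses, had 6.66 ± 1.17, adjusted p = 0.0177, and the replication licensing factor MCM5 (CL2091.Contig1) 4.63 ± 0.92, adjusted p = 0.0229. Reticuline oxidase-like protein CL10187.Contig1, at least 210-fold higher, belonged to set C and so was present in 6 h replicate 2 and absent from 6 h replicate 1. Lower were a DNA glycosylase (Unigene11616), an enzyme of base excision repair (-5.95 ± 0.70, adjusted p = 0.0108), cyclin-D3-1 (Unigene2930), of cell division (-7.22 ± 1.65, adjusted p = 0.0304), and bHLH155 (Unigene3002), at least 77.0-fold lower.

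WRKY factors (27 of 150 rose and 4 fell; 32 and 5 adjusted over the list alone), root and vascular markers (12 of 38 rose and 1 fell; 13 and 2 adjusted over the list alone) and microbial and animal sequences (34 of 174 rose and 2 fell; 38 and 2 adjusted over the list alone) were higher by camera (adjusted p = 0.00638, 0.00954 and 0.00488). Cell cycle genes (3 of 324 rose and 34 fell; 3 and 21 adjusted over the list alone), bHLH factors (12 of 140 rose and 25 fell; 16 and 37 adjusted over the list alone) and antioxidant enzymes (22 of 353 rose and 31 fell; 21 and 31 adjusted over the list alone) were lower (adjusted p = 0.00488, 0.0145 and 0.0145). With an estimated correlation the adjusted p of these 6 lists ran from 0.414 to 0.563, and with the set as a term WRKY factors (0.0289) and root and vascular markers (0.0202) stayed under 0.05. The antioxidant list then had a median of 0.04 (adjusted p = 0.676). WRKY6 (CL5875.Contig2) was at least 17.8-fold higher. Leaving out 1 library raised the adjusted p to 0.112 for WRKY and 0.178 for antioxidant (0 h replicate 3), 0.0865 for root and vascular (0 h replicate 2) and 0.0768 for bHLH genes (recovery replicate 2), and the other 5 of the 9 lists called stayed called. With the set as a term edgeR called 0 unigenes in recovery, with 9071 at an unadjusted p under 0.05. Without that term limma-voom called 2950 (1268 higher, 1682 lower) and DESeq2 11637 (6543 higher, 5094 lower). Leaving out recovery replicate 1 gave 1140 calls (959 higher, 181 lower), recovery replicate 2 0 by edgeR (with 10235 at an unadjusted p under 0.05), 0 h replicate 2 12528 and 0 h replicate 3 4161. A model of these 2 groups alone gave 3712.

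**Figure D3:**
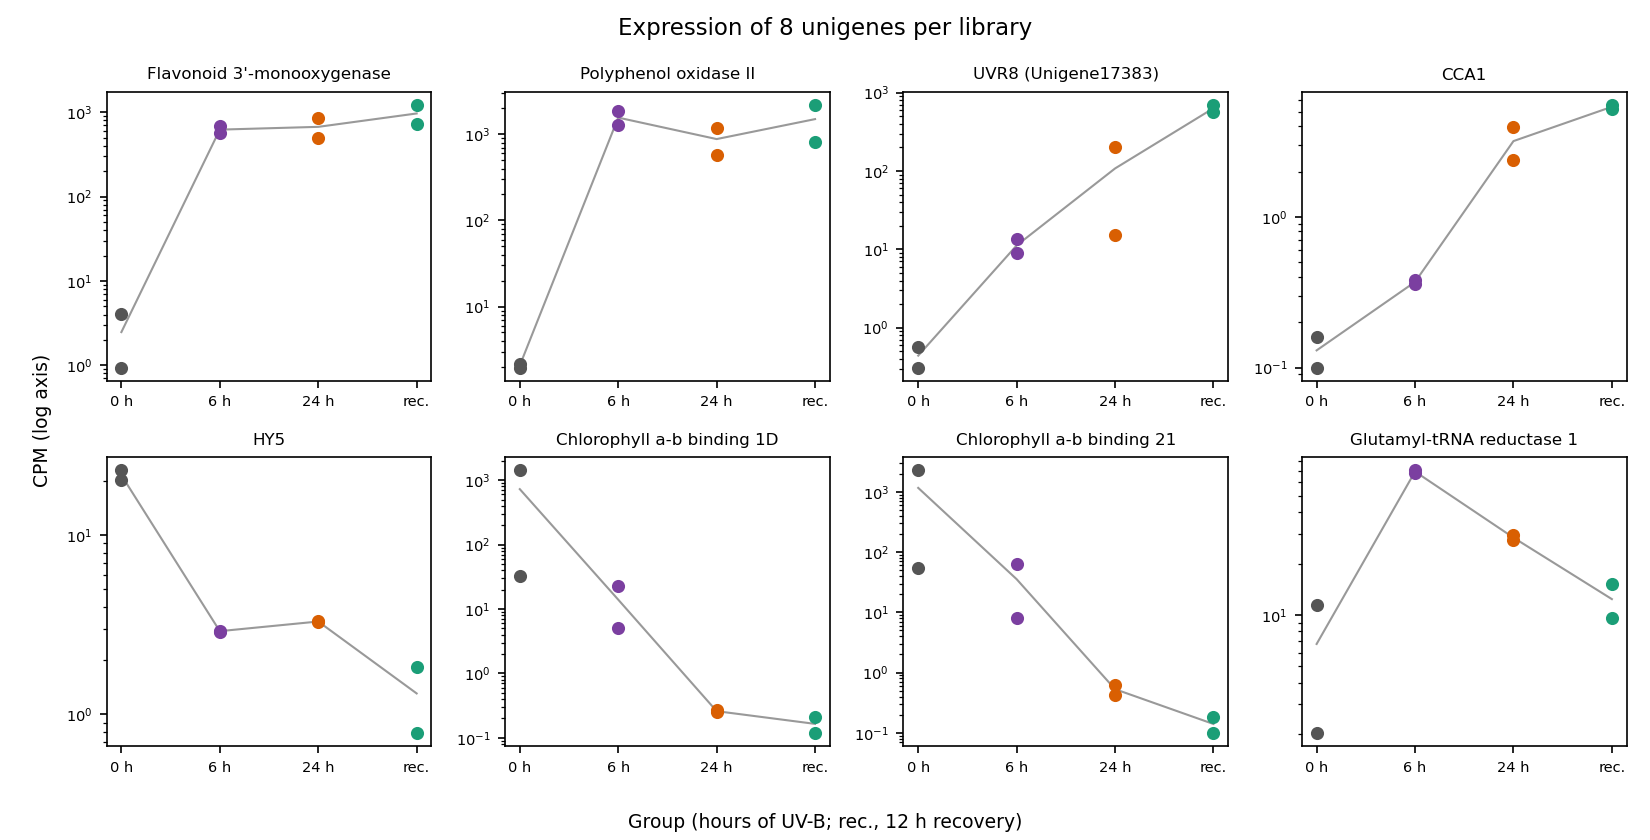
CPM (log axis, 0 drawn at 0.1) of 8 unigenes in each of the 8 libraries, 1 point per library, with groups in order of time on the horizontal axis and a line through the group means. Flavonoid 3'-monooxygenase, polyphenol oxidase II and UVR8 (Unigene17383) lie above their 0 h values in every other library, and HY5 and chlorophyll a-b binding protein 1D lie below theirs.

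The 3 comparisons with 0 h shared many calls. Between 6 h and 24 h 2989 unigenes were higher in both and 1370 lower in both, against 392 and 156 for independent lists of those sizes. Between 6 h and recovery 2618 were higher and 1585 lower in both (449 and 241 for independent lists), and between 24 h and recovery 2592 and 1562 (309 and 144). In all 3 comparisons 2230 unigenes were higher and 1079 lower. The log2 changes correlated with Pearson r of 0.812, 0.726 and 0.901 across unigenes, which are not independent replicates, against 0.680, 0.682 and 0.766 in 20 simulations of unchanged groups that shared simulated 0 h libraries. Their covariances were 5.26, 4.95 and 6.20 against 0.746, 0.746 and 0.743, differences of 4.51, 4.20 and 5.46. Part of the excess over independent lists may come from the shared 0 h libraries, which are too few to split. The simulations held no difference between library sets. The excess over them therefore cannot separate the exposure from the sets or from the state of the real 0 h libraries. Across all 4 groups 6785 unigenes differed by the edgeR F test, and 776 of 40978 did among the 3 groups other than 0 h in a model without the 0 h libraries.

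The 24 h group was compared with the 6 h group. No unexposed seedlings were sampled at these times, so the length of exposure cannot be told apart from time of day and age. The model of all 4 groups called 0 unigenes by edgeR, with 4221 at an unadjusted p under 0.05, while limma-voom called 1 and DESeq2 509. An edgeR model without the 0 h libraries called 0 as well, with 6703 at an unadjusted p under 0.05. The genes named here are calls of DESeq2, a choice made after these counts were seen. Defensin-like protein 1 (CL11724.Contig1), an antimicrobial peptide, was at least 43.8-fold higher at 24 h (adjusted p = 5.05e-05), with no fragment at 6 h. Higher as well were cinnamoyl-CoA reductase 2 (Unigene20508), of lignin synthesis, with a log2 change of 5.17 ± 0.93, adjusted p = 2.49e-05, costunolide synthase (CL11604.Contig2), of sesquiterpene lactone synthesis, with 4.76 ± 1.16, and MYB90 (CL4152.Contig1), an activator of anthocyanin synthesis, with 3.76 ± 0.87. Poly(ADP-ribose) polymerase 2 (CL8095.Contig1), a sensor of DNA breaks, had 2.99 ± 0.82, heat stress factor B-3 (Unigene15840) 3.83 ± 0.77 and CCA1 (CL7209.Contig2) 3.04 ± 0.83. Early light-induced protein 1 (CL4363.Contig2), which protects chloroplasts in strong light, had 1.75 ± 0.52, and UVR8-described Unigene17383 3.19 ± 0.95, adjusted p = 0.0469.

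Lower at 24 h than at 6 h were a Rubisco small chain (Unigene33658, -8.38 ± 1.50, adjusted p = 2.32e-05), beta-caryophyllene synthase (Unigene10693, -6.71 ± 1.38), anthocyanidin 3-O-glucosyltransferase 2 (CL860.Contig7, -6.40 ± 1.61) and glutaredoxin-S1 (CL5367.Contig3, -6.04 ± 1.10). The same direction held for ERF017 (Unigene33860, -5.48 ± 1.20), WRKY70 (CL4961.Contig1, -3.42 ± 0.89), a jasmonate-induced 23 kDa protein (Unigene7393, -4.32 ± 1.07) and SAUR19 (CL7016.Contig2, -4.12 ± 1.00). By camera in the model of all 4 groups, photosynthesis genes (median -1.13), jasmonate (-0.64), ethylene (-0.43), auxin (-0.68), phenylpropanoid (-0.77), WRKY (-0.45) and cell wall genes (-0.37) were lower and DNA repair genes (0.58) higher. Their adjusted p were 2.42e-07, 2.42e-07, 7.92e-05, 1.07e-04, 6.17e-04, 0.00114, 0.0292 and 0.00534. With an estimated correlation the adjusted p ran from 0.391 to 0.691. Adjusted over the list alone, 5 jasmonate genes fell and no member of the other 7 lists was called. Leaving out 1 library ended the calls of cell wall (adjusted p up to 0.659) and DNA repair genes (0.0603). Within set C, the medians over 24 h against 6 h replicate 2 were -0.27, -0.68, -0.39, -0.28, -0.39, -0.33, -0.02 and 0.41; with the set as a term the cell wall list had an adjusted p of 0.672 and the other 7 stayed under 0.05.

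Recovery was also compared with 6 h of UV-B, the widest interval among the exposed groups. The model of all 4 groups called 0 unigenes by edgeR (9423 at an unadjusted p under 0.05), limma-voom 1760 and DESeq2 3539, and a model without the 0 h libraries called 3568, 1513 higher and 2055 lower. The latter was chosen after the spread between the 0 h libraries was seen, and its values are given here. By camera 13 lists were called in it, 11 lower and 2 higher, and 0 with an estimated correlation. Jasmonate O-methyltransferase (Unigene33785), which makes methyl jasmonate, was at least 50.9-fold lower (adjusted p = 0.0333), WRKY41 (CL4628.Contig2) had -4.59 ± 0.81, adjusted p = 0.0278, and laccase-4 (CL5919.Contig1), of lignin polymerisation, -7.71 ± 1.52, adjusted p = 0.0334. Chlorophyll a-b binding protein 21 (CL432.Contig6) had -7.98 ± 1.21, adjusted p = 0.0233, glutamyl-tRNA reductase 1 (CL1157.Contig1) -2.48 ± 0.32, adjusted p = 0.0233, and ribosomal protein L14-2 (Unigene10018) -1.95 ± 0.36, adjusted p = 0.0300. Catalase (CL1641.Contig2), which removes hydrogen peroxide, rose from 139 ± 79.0 to 671 ± 132 CPM (log2 change 2.28 ± 0.55, adjusted p = 0.0479).

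Cinnamoyl-CoA reductase 2 (Unigene20508) had a log2 change of 5.99 ± 0.48, adjusted p = 0.0233, dihydroflavonol 4-reductase (Unigene15999), of anthocyanin synthesis, 3.38 ± 0.49 and UVR8-described Unigene17383 5.83 ± 1.14, adjusted p = 0.0330. The mismatch repair protein MSH4 (CL5535.Contig8) had 5.03 ± 0.63, pheophytinase (CL2461.Contig4) 2.90 ± 0.44, NAC100 (CL124.Contig2) 5.55 ± 0.86, MYB108 (CL3732.Contig2) 2.86 ± 0.43, a proteinase inhibitor (CL7657.Contig2) 7.67 ± 1.40 and defensin-like protein 1 (CL11724.Contig3) 6.83 ± 0.90. In the model without the 0 h libraries 7 of 146 WRKY factors rose and 37 fell, and of the photosynthesis genes 0 of 219 rose and 43 fell. Jasmonate genes (3 of 96 rose, 24 fell), phenylpropanoid enzymes (3 of 69 rose, 17 fell) and ethylene genes (8 of 219 rose, 36 fell) were lower too, and senescence genes (15 of 125 rose, 4 fell) and DNA repair genes (8 of 126 rose, 1 fell) higher. Camera adjusted p were 7.15e-08, 1.22e-07, 7.72e-05, 2.96e-05, 0.00980, 0.00137 and 0.0389, and with an estimated correlation between 0.450 and 0.568. The other 6 lists called were lower: ribosomal proteins (median -0.66, adjusted p = 7.72e-05), gibberellin and brassinosteroid (-0.74, 0.00280), auxin (-0.62, 0.0212), defence (-0.39, 0.0370), NAC (-0.77, 0.0370) and terpenoid genes (-0.62, 0.0389). Their adjusted p with an estimated correlation ran from 0.450 to 0.611. Terpenoid genes were not called in the model of all 4 groups (camera adjusted p = 0.0536). With the set as a term, which rests on 6 h replicate 2, auxin, NAC and terpenoid genes were not called (medians -0.34, -0.32 and -0.48). In the model of all 4 groups the calls of senescence (0.374 as an adjusted p without 6 h replicate 2), DNA repair (0.0600), ribosomal (0.0718), defence (0.114) and NAC genes (0.147) ended when 1 library was left out. Adjusted over the list alone in the model of all 4 groups, 3 WRKY factors rose and 18 fell, and 5 jasmonate genes rose and 23 fell. Within set C the medians against 6 h replicate 2 were -1.13 for WRKY, -0.44 for photosynthesis, -0.64 for jasmonate and 0.55 for senescence genes.

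Recovery was set against 24 h of UV-B, 12 h after the light was switched off, and all 4 libraries lay in set C. Time of day and age can differ between these groups as well, with no unexposed seedlings at either time. The model of all 4 groups called 0 unigenes by edgeR (3468 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 322. An edgeR model without the 0 h libraries called 0 too (6100 at an unadjusted p under 0.05). The calls of DESeq2 are named here, a choice made after the counts were seen. The 2-oxoglutarate-dependent dioxygenase AOP1.2 (Unigene22109) was at least 30.1-fold higher (adjusted p = 0.00933), the ethylene-responsive factor RAP2-11 (Unigene21913) had 6.34 ± 1.67, adjusted p = 0.0238, and vacuolar-processing enzyme (Unigene11020), a protease of vacuolar proteins, 5.25 ± 1.43. Laccase-14 (CL3611.Contig2) had 3.29 ± 0.58, adjusted p = 6.84e-05, xyloglucan endotransglucosylase 15 (Unigene9932), which loosens cell walls, 3.49 ± 0.82, and the jasmonate-induced 23 kDa protein (Unigene7393) 4.50 ± 1.07. Lower were NAC90 (CL2969.Contig1), by at least 20.8-fold, germacrene A synthase (CL610.Contig1, -4.19 ± 0.89, adjusted p = 0.00219), the receptor-associated kinase BAK1 (CL5387.Contig3, -4.17 ± 0.91), a PR-1 type protein (CL10321.Contig3, -3.77 ± 0.90) and WRKY41 (CL4628.Contig2, -3.17 ± 0.89). Flavonoid 3'-monooxygenase Unigene9542 had -2.33 ± 0.62, caffeoyl-CoA O-methyltransferase (CL1060.Contig5) -2.18 ± 0.56 and allene oxide cyclase 3 (CL1381.Contig2), of jasmonate synthesis, -2.72 ± 0.78.

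By camera in the model of all 4 groups, cytosolic ribosomal proteins were lower in recovery than at 24 h (513 measured, median -0.74, adjusted p = 5.29e-11), and so were WRKY factors (-0.78), terpenoid enzymes (-0.54), gibberellin and brassinosteroid genes (-0.43), lignin enzymes (-0.35) and defence genes (-0.25). Senescence genes (0.51), latex and wound markers (0.34) and microbial and animal sequences (0.23) were higher. Their adjusted p ran from 3.61e-05 to 0.0158 after the ribosomal proteins, and with an estimated correlation from 0.779 to 0.842. Adjusted over the list alone 7 terpenoid enzymes fell and no member of the other 8 lists was called. Without recovery replicate 2 the calls of defence (adjusted p = 0.234), latex and wound (0.0601) and microbial and animal sequences (0.255) ended. Photosynthesis genes had a median of 0.00 (adjusted p = 0.379), or -0.28 in the model without the 0 h libraries (adjusted p = 0.0229, 0.726 with an estimated correlation), and UV-B and light signalling genes -0.04 (adjusted p = 0.379). In the model of Asteraceae best hits alone, the light signalling list was higher by camera (median 0.26, adjusted p = 0.00354), though of its 87 members 0 rose and 0 fell. Against 6 h that list was higher there too (0.31, camera adjusted p = 0.0290), again with 0 members called. No estimated correlation was taken in that model.

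**Figure D4:**
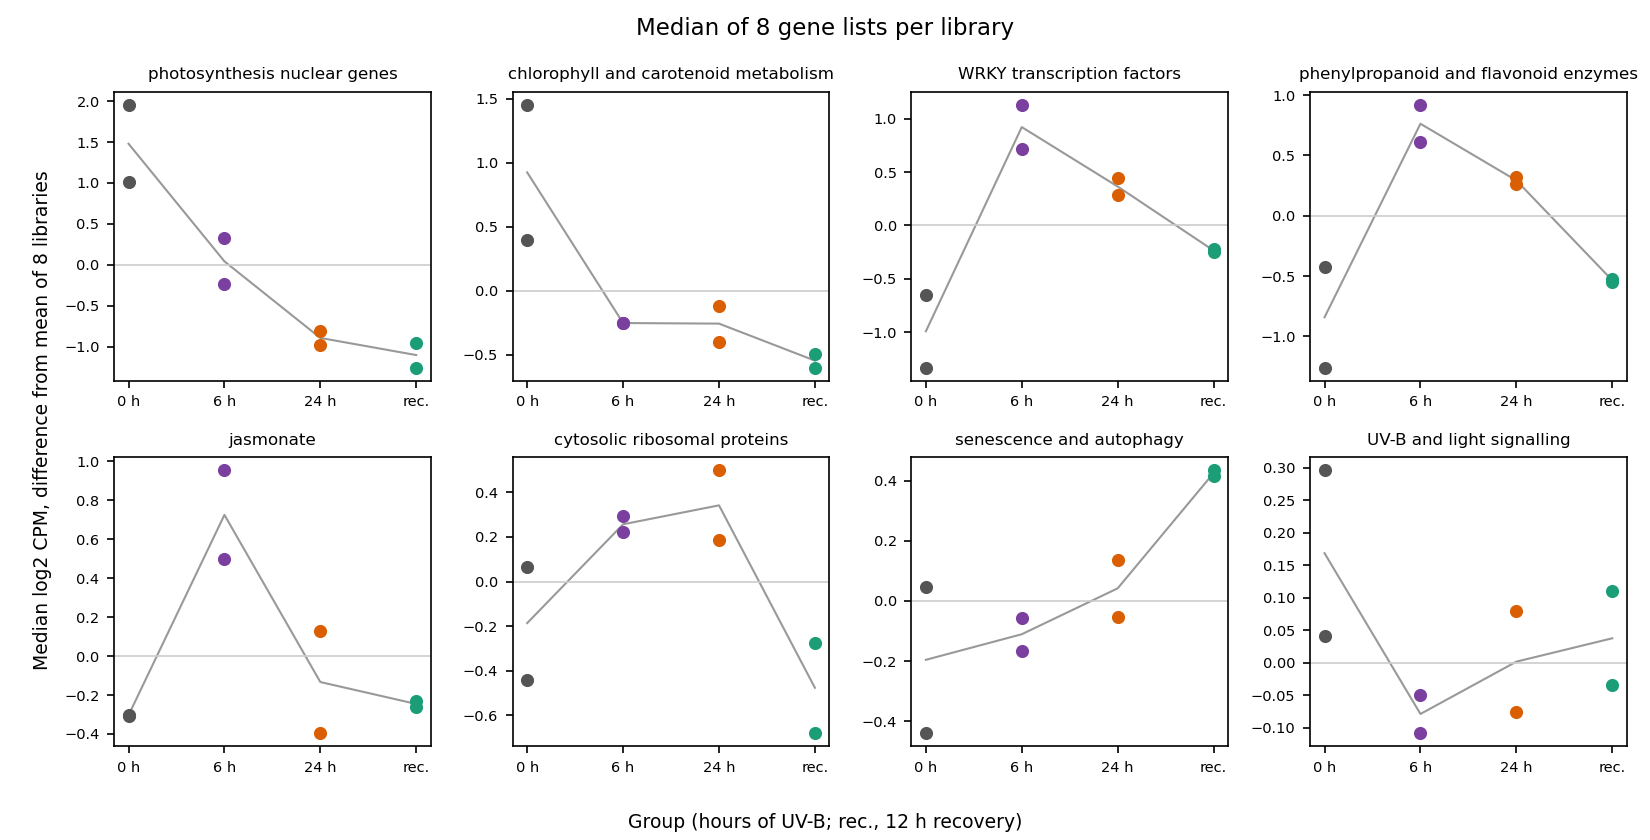
Median log2 CPM of 8 gene lists in each of the 8 libraries, as the difference from each unigene's mean over the 8 libraries, 1 point per library, in order of time on the horizontal axis. The photosynthesis list is highest in the 0 h libraries and the WRKY list in the 6 h libraries.

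Whether changes at 6 h went back after the exposure ended was read from signs, since the model of all 4 groups called no unigene between recovery and 24 h. Of 8626 unigenes changed at 6 h with a sign in both comparisons, 5000 (58.0%) moved the opposite way between 24 h and recovery, against 51.7% from the margins (exact binomial p = 8.3e-32, unigenes not being independent). Of those raised at 6 h 64.4% were lower in recovery than at 24 h, and of those lowered at 6 h 48.2% were higher. The share was 49.6% (margins 49.4%) without 0 h replicate 2 and 48.8% (margins 54.3%) without recovery replicate 1. It was 71.0% (margins 51.8%) of the unigenes called at 6 h in the model with the set as a term. Of all tested unigenes with a sign it was 52.8% (margins 49.0%).

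The authors' deposited table listed 733 unigenes as higher and 53 as lower for 6 h against 0 h, and the ratio had the sign opposite to the label in 118 of these. The authors' deposited table listed 1022 higher and 170 lower for 24 h against 0 h, and 1091 and 265 for recovery against 0 h. For 24 h against 6 h the authors' deposited table listed 89 higher and 182 lower, for recovery against 6 h 1065 and 1000, and for recovery against 24 h 404 and 262. The authors' deposited tables gave a ratio of opposite sign to the label in 5 unigenes for 24 h against 6 h and in 5 for recovery against 24 h.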

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

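The alternatives with the library set as a term, with Asteraceae best hits alone, with limma-voom and without the 0 h libraries, the reversal with DESeq2 and, for gene lists, leaving out 1 library and the replicate block, were chosen after the data were seen. The cause of a difference was not tested unless a value is given for it.

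The counts of unigenes changed against 0 h stayed within 1.5 times with DESeq2 size factors, without a low-count filter, with Asteraceae best hits alone and at 2-fold. DESeq2 gave 12349 at 6 h, also within 1.5 times, and 10059 at 24 h and 11637 in recovery. Limma-voom gave 1643 at 6 h, 1783 at 24 h and 2950 in recovery, models of only the compared groups 0, 2136 and 3712, and an adjusted p under 0.01 gave 755, 311 and 54. With the library set as a term the counts were 5329 at 6 h, 0 at 24 h and 0 in recovery; at 24 h and in recovery this term leaves no library of the same set at 0 h. With a replicate block they were 2056, 1751 and 1242, although the replicate numbers do not pair the libraries, since the log2 ratios of replicates 1 and 2 correlated between groups with r of -0.26, -0.007 and 0.022.

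Leaving out 1 library gave 1773 to 12497 unigenes at 6 h, 579 to 10427 at 24 h and 0 to 12528 in recovery, and 0 in every such model for the 3 comparisons without 0 h; a lone library is then assumed to vary like the other groups. For 24 h against 6 h DESeq2 called 509, limma-voom 1 and a model without the 0 h libraries 0. For recovery against 6 h DESeq2 called 3539, limma-voom 1760, a model of only these groups 3040 and a model without the 0 h libraries 3568. For recovery against 24 h DESeq2 called 322 and a model without the 0 h libraries 0. Over the whole course 776 unigenes differed without the 0 h libraries, in a test of 3 groups, against 6785 of 4.

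No list was called with an estimated correlation (0 in each of the 6 comparisons, and 0 in the 3 without 0 h when its libraries were left out), against 13, 17, 9, 8, 12 and 9. With the library set as a term 8 lists were called at 6 h and 9 at 24 h. Counting 1 unigene per description gave 11 at 24 h, 5 in recovery against 0 h and 5 in recovery against 24 h. With Asteraceae best hits alone 14 lists were called in recovery. Without 0 h replicate 3, 8 lists were called higher and 0 lower at 6 h, against 9 and 4. Leaving out 1 library gave 8 to 14 lists at 6 h, 12 to 15 at 24 h, 9 to 15 in recovery, 8 to 10 for 24 h against 6 h, 10 to 13 for recovery against 6 h and 7 to 9 for recovery against 24 h. The overlaps at 4-fold stayed within 1.5 times.

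The share of unigenes changed at 6 h that moved the opposite way between 24 h and recovery ran from 48.8% to 74.4% when 1 library was left out. Without recovery replicate 1 it was below the share from the margins, and without 0 h replicate 2 (49.6%, exact binomial p = 0.786) or 6 h replicate 1 (62.8%, exact binomial p = 0.323) it was not told apart from it.

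Of the genes named from edgeR comparisons with 0 h, 25 stayed called and 61 did not in the model without the library that gave the largest adjusted p, all in the same direction. With the library set as a term 23 named values stayed called, 109 kept their direction without being called, and 1 turned, leucoanthocyanidin dioxygenase CL9596.Contig1 in recovery, at 0.13. With DESeq2 98 stayed called and 4 did not. All 47 values read from other models were in the same direction and not called in the edgeR model of all 4 groups, which called 0 unigenes there. Named genes had to have libraries that do not overlap between the compared groups. Leaving out 1 library could therefore hardly turn a direction, and the kept directions are not separate evidence. Every gene named in recovery against 0 h was among those not called when a library was left out, since leaving out recovery replicate 2 gave 0 calls.

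The planned changes of pseudocount, authors' fold, expression floor and list background were not run, since they apply to normalized values or to deposited calls alone. The depth put the floor of a unigene without fragments at 0.163 to 0.235 CPM.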

Other observations

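The tests of an exchange of libraries, of the level in 0 h replicate 3, at 24 h and at 6 h, of the course over time, of the library sets behind the photosynthesis change and of the groups behind the sets were chosen only after the result was seen, and so were the gene families below.

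Outside the 30 lists 12 families were tested, and some of them are given here. Receptor-like kinases were higher at 6 h of UV-B than at 0 h: 399 of 1514 rose and 57 fell (median log2 change 1.13, camera adjusted p = 9.38e-08, adjusted p = 0.190 with an estimated correlation). At 24 h 299 rose and 42 fell, and in recovery 220 and 108 (camera adjusted p = 3.99e-06 and 0.0974; adjusted p = 0.160 and 0.596 with an estimated correlation). Calcium-binding proteins went the same way, with 65 of 253 higher and 3 lower at 6 h (median 1.08, camera adjusted p = 1.28e-07, adjusted p = 0.0580 with an estimated correlation). Starch enzymes fell: 22 of 85 at 6 h, 10 at 24 h and 21 in recovery, with medians of -1.91, -2.30 and -2.28 (camera adjusted p = 2.93e-06, 3.07e-08 and 4.74e-07). Their adjusted p were 0.329, 0.243 and 0.452 with an estimated correlation and 0.0540, 0.0390 and 0.0194 with the set as a term. Of 74 aquaporins 15 fell and 1 rose at 24 h, and 16 fell and 0 rose in recovery (camera adjusted p = 4.01e-06 and 6.60e-05, 0.406 and 0.591 with an estimated correlation, 0.124 and 0.125 with the set as a term). At 6 h 9 fell and 5 rose (camera adjusted p = 0.0563). Without the 0 h libraries only 54 of the starch enzymes and 49 of the aquaporins passed the low-count filter, so the others were low in the later groups. Cytochrome P450 were higher at 6 h (70 of 242 rose and 14 fell, camera adjusted p = 1.56e-05, adjusted p = 0.190 with an estimated correlation).

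The 2 libraries at 0 h differed more than the replicates of any other group. An exchange with another group was argued against, since the highest correlation of each was with the other (Pearson r = 0.816) and 0 libraries had their best partner across the divide between 0 h and the other groups. A different time of day at harvest stays open: the clock list's ratio lay at percentile 80.4 of random lists for its 69 expressed members and at 46.9 for all 79, and the restriction to expressed members was set after the first value was seen. A sugar-starved state of replicate 2 stays open too, at percentile 63.5 for 48 expressed members of amino acid breakdown and 37.3 for all 74.

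Sequences with best hits in other organisms divided the libraries into sets A, B and C. The groups themselves were argued against, since 2 groups were divided between sets. Preparation or sequencing in batches stays open and, for 24 h and recovery against 0 h, cannot be told apart from the treatment. The log2 ratios of set A over another set in the 0 h and the 6 h group correlated with r = -0.075 across 45866 unigenes, under the bound of 0.1 written before, but that bound was wrong to exclude batches that bring in sequences without moving lettuce genes, and other pairs of replicate ratios reached 0.29 in size. No biological explanation was tested.

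Photosynthesis genes were lower after UV-B and in recovery than at 0 h. A high level in 0 h replicate 3 alone was argued against at 24 h by the median log2 change of -1.82 against replicate 2, but only for the list of 331 as a whole. Replicate 2 and the 24 h libraries lie in different sets, so sequences of other organisms may add to that value. No median against replicate 2 alone was taken at 24 h over the 128 members with an Asteraceae best hit, so for them this explanation stays open. At 6 h it stays open for the whole list, which was not called without replicate 3 (camera adjusted p = 0.0574, median -0.91 against replicate 2). The library sets stay open as a cause: with the set as a term of the edgeR model the list was lower at 24 h and in recovery (camera adjusted p = 1.54e-04 and 2.68e-06, 1.03e-05 and 8.94e-08 unadjusted) and not at 6 h (adjusted p = 0.720, 0.504 unadjusted), but the medians went from -3.79 to -0.59 at 24 h and from -4.21 to -0.78 in recovery (from -3.26 to -1.26 and from -3.48 to -1.84 over the 128 members with an Asteraceae best hit), only the 6 h libraries link these groups to 0 h in that model, and an estimated correlation without the term gave adjusted p of 0.289 and 0.414. A change that goes on under and after UV-B stays open: in the edgeR model without the 0 h libraries the list fell from 6 h to recovery (camera adjusted p = 1.22e-07, 8.14e-09 unadjusted; adjusted p = 0.450 with an estimated correlation), but from 24 h to recovery the median was -0.28 there (adjusted p = 0.0229, 0.726 with an estimated correlation) and 0.00 in the model of all 4 groups (adjusted p = 0.379). Growth stage differs from 0 h in every group, by the hours since the start. If all groups started at the same hour, time of day differs at 6 h and in recovery but not at 24 h. No clock time of harvest was found in the labels. Neither growth stage nor time of day was tested, so the exposure may not be the source of the whole change.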
